A study of Mus musculus with 6 samples.

How the data were processed

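Circular RNAs (circRNAs), closed RNA loops formed by back-splicing, were measured by 1-colour microarray in BV2 cells, an immortalized mouse microglial line. The 6 arrays analysed were 3 of cells given IL-4 at 10 ng/ml for 24 h and 3 of cells given PBS for 24 h. Groups and replicate numbers were taken from the sample titles. The labels are not uniform: the sample descriptions also mention human blood, whereas the organism, cell line and protocols name mouse BV2 cells, and the series design text calls the controls untreated, whereas the titles and the treatment protocol name PBS. Per the labels' protocols, total RNA was digested with RNase R, an exonuclease that degrades linear RNA, and the remaining RNA was labelled with Cy3 by random priming. Incomplete digestion would leave linear RNA that can hybridise, and differences in digestion between samples would enter every signal.

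Per the file headers, spots were quantified by Agilent Feature Extraction 11.0.1.1, and all 6 arrays carry 1 scan time and 1 photomultiplier setting. The deposited intensity of each spot is the processed signal, which Feature Extraction background-subtracts and detrends within the array, with no normalization between arrays. The fit value that the headers give for multiplicative detrending was 0 on PBS replicate 1 and 0.018 to 0.052 on the other arrays. Whether that step was applied to PBS replicate 1 was not checked. The spot and local background median intensity columns were also used. Each array holds 14236 circRNA probes with 1 spot each and 94 further design probes with 10 spots each. By their names, 50 of these are catalogue-style probes, 15 custom probes, 14 circRNA controls and 15 negatives. The whole-series table holds log2 values of the 14236 circRNA probes as deposited by the authors. In every array its ranks equalled those of the median signal minus the median background (Spearman 1), and its medians lay between 6.51 and 6.52 with a common maximum of 17.0, so it is quantile-normalized and on a positive log2 scale. The exact background step behind it is not given in the sources used here. The submitters' processing notes name Agilent Feature Extraction and limma, without a role for either.

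From the files, log2 of the processed signal minus each array's 75th percentile over the circRNA probes was computed. Spots with outlier flags (2 or fewer circRNA spots per array) were left out, and no circRNA spot was saturated. A probe entered when it was well above background on all 3 arrays of at least one group, which held for 14062 probes and left out 174. IL-4 was compared with PBS by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, all 6 arrays, no covariate, two-sided), with Benjamini-Hochberg adjustment over the 14062 probes and a threshold of adjusted p under 0.05. Counts at an unadjusted p under 0.05 with a difference of at least 1.5-fold are given as well. The procedure was tested on simulated data in which 200 of the 14062 probes were changed, with the probes' own means and moderated spread.

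The design, the settings and the rule for named probes were fixed before the data were examined. The rule took the 10 probes of largest difference in each direction among those past the threshold. As none passed, it was filled by lowest unadjusted p among probes whose groups did not overlap. Of these, 2 per direction are named by probe ID, and ASCRP4009598 is given besides for the size of its difference. The files pair no probe ID with a circRNA name, host gene or genomic position, and no such table was used here. The planned tests of host genes, of host gene lists and of circRNA classes were therefore not run.

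The background flag passed between 97.9% and 99.8% of circRNA probes per array. The 15 negatives had median signals of 29.6 to 40.6 and maxima of 132 to 247, so an alternative filter used their 95th percentile on each array. The brightest negatives, MM9NEGATIVE016 and MM9NEGATIVE017, set that percentile. The planned background correction (normexp, offset 50) was run on the median signal, because the files hold no mean signal. Other alternatives were quantile normalization, other scalings and filters, the deposited value table, a replicate block, array weights, other thresholds and leaving out each array. Added after seeing the data were cyclic loess, the filter by negatives, the array's position row as a block or the first row alone, and combined settings without PBS replicate 3. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples. The number of arrays limits the precision.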

Results

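The study asked how the circRNA profile of microglia shifts when they are driven toward the M2 state, the alternatively activated state that the type 2 cytokine IL-4 induces in macrophages and microglia. RNase R-treated RNA from 3 BV2 samples given IL-4 at 10 ng/ml for 24 h and 3 given PBS was hybridised to 6 arrays of 14236 circRNA probes. Median processed signals of the circRNA probes, already background-subtracted, ranged from 69.1 to 83.6 per array. The local background before subtraction had a median of 17, which is not on the same scale. The probes named as negatives reached 132 to 247, and 13.7% to 24.7% of circRNA probes per array lay above all 15 of them. Most circRNA probes were therefore read in the range that negatives also reached. The top of that range came from MM9NEGATIVE016 and MM9NEGATIVE017. Relative to the array's 75th percentile, their mean log2 signals were 0.29 and 0.02 with IL-4, and 0.57 and 0.14 with PBS. The next brightest negative, MM9NEGATIVE008, had -0.92 with IL-4 and -1.16 with PBS. Per array, 9.12% to 16.8% of circRNA probes lay below the negatives' median.

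The 6 circRNA profiles were close to one another, and they did not separate by treatment on the first principal component. Across probes, which are not independent replicates, the 3 IL-4 arrays correlated with one another at a mean Pearson r of 0.989 ± 0.00353 (SD, 3 pairs). The 3 PBS arrays correlated at 0.974 ± 0.0106 (SD, 3 pairs), and the 9 pairs across groups at 0.979 ± 0.00765 (SD). PBS replicate 3 correlated with IL-4 replicates 1, 2 and 3 at 0.987, 0.988 and 0.984, and with PBS replicates 1 and 2 at 0.979 and 0.962. The first principal component held 51.3% of the variance. On it PBS replicate 3 scored -15.9, beside IL-4 replicates 1 and 2 at -14.4 and -12.3. IL-4 replicate 3 scored 0.99, and PBS replicates 1 and 2 scored 11.9 and 29.6. The median SD of a circRNA probe was 0.12 on the log2 scale among the IL-4 arrays and 0.18 among the PBS arrays, against 0.08 between the 10 spots of a design probe within an array.

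**Figure D1:**
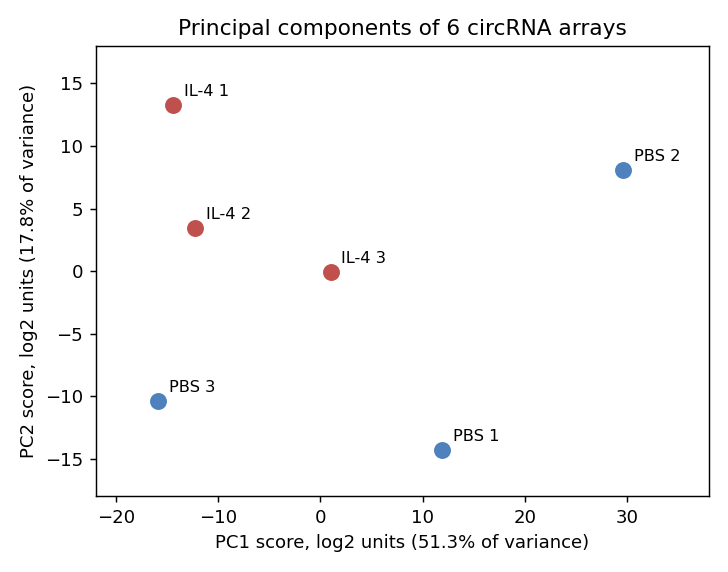
Scores of the 6 arrays on the first (x axis, 51.3% of variance) and second (y axis, 17.8%) principal components of the log2 circRNA signals, in log2 units, with IL-4 arrays in red and PBS arrays in blue. PBS replicate 3 (-15.9) lies at the same end of the first component as IL-4 replicates 1 (-14.4) and 2 (-12.3).

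The comparison of IL-4 with PBS asked which circRNAs changed in level with treatment. With all 6 arrays, 0 of 14062 circRNA probes passed an adjusted p under 0.05 (limma, Benjamini-Hochberg), and the lowest adjusted p was 0.247. At an unadjusted p under 0.05 there were 909 probes, 582 higher and 327 lower in IL-4, where 703 would be the mean count by chance. Other splits of the 6 arrays into 3 and 3 gave from 77 to 3016. The 3016 came from the split that exchanges IL-4 replicate 3 with PBS replicate 3, and no other exceeded 733. The splits are too few for a share under 0.05, so 909 is not shown to be an excess. With all 6 arrays the median absolute log2 difference was 0.12 and the median standard error 0.14, and 3 probes differed by 2-fold or more at any p. Without PBS replicate 3 that number was 46, 8 higher and 38 lower, of which 43 passed the adjustment, and the highest difference was 6.09-fold downward against 2.37-fold with all arrays. It was 23 without IL-4 replicate 3, 12 without IL-4 replicate 2, 6 without IL-4 replicate 1, 7 without PBS replicate 2 and 3 without PBS replicate 1. The 95% interval of a probe's difference had a median half-width of 0.31 on the log2 scale, or 1.24-fold. In data simulated for this comparison on 14062 probes, 2-fold changes were recovered in 99.2% of the changed probes and 1.5-fold changes in 44.1%. These simulated data had independent noise of equal spread on all arrays, unlike the real arrays, which differed in spread between the groups. The shares therefore do not tell how many real changes would be found. With all 6 arrays ASCRP4009598 differed by 2.03-fold at a limma adjusted p of 0.247. It ranked 5 by p among probes higher in IL-4 without overlap and is given for its size. Its signal exceeded the 95th percentile of the negatives on 1 of the 6 arrays.

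A group of 112 probes had an unadjusted p under 0.05 and a difference of at least 1.5-fold, 75 higher and 37 lower in IL-4 (67.0% higher). Their median difference was 1.60-fold, the highest 2.15-fold upward and 2.00-fold downward, and none passed the adjustment. The balance of directions moved with the scaling and background correction: 55 were higher and 40 lower with quantile normalization, 17 higher and 34 lower in the deposited value table, and 8 higher and 15 lower with normexp and percentile scaling. It also moved with single arrays: 252 were higher and 243 lower without PBS replicate 3, 114 and 121 without IL-4 replicate 3, and 92 and 24 without PBS replicate 2. With all 6 arrays, 13 of the 75 higher and 17 of the 37 lower probes exceeded the 95th percentile of the negatives on every array. Among all 14062 tested probes, 2313 did. In 11.3% of all probes the 3 IL-4 values lay entirely above or below the 3 PBS values, where chance gives 10%.

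Among probes with higher values in IL-4 and no overlap between the groups, the lowest p belonged to ASCRP4001641 and ASCRP4003985. ASCRP4003985 had a processed signal of 1298 ± 165 (SD, n = 3) with IL-4 and 831 ± 52.1 (SD, n = 3) with PBS. Its log2 difference was 0.72 (95% interval 0.46 to 0.98, 1.65-fold, limma adjusted p = 0.247). ASCRP4001641 was dim, at 59.0 ± 9.12 with IL-4 and 36.0 ± 3.87 with PBS (SD, n = 3 each), and stayed under the 95th percentile of the negatives on every array. Its log2 difference was 0.79 (1.73-fold, limma adjusted p = 0.247), but 0.40 with normexp and percentile scaling, 0.36 with normexp and quantile normalization and 0.55 in the deposited value table. Among probes with lower values in IL-4, ASCRP4006403 measured 607 ± 144 with IL-4 and 1249 ± 249.6 with PBS (SD, n = 3 each), a log2 difference of -0.96 (95% interval -1.31 to -0.61, limma adjusted p = 0.247). ASCRP4000589 measured 195 ± 30.3 and 414 ± 110.3 (SD, n = 3 each), a log2 difference of -0.98 (limma adjusted p = 0.247). In both of these the PBS replicate 3 signal, 962 and 287, lay between the other PBS arrays and the IL-4 arrays. Among probes whose groups did not overlap, the 10 of lowest p in each direction differed by 1.53-fold to 2.03-fold upward and by 1.53-fold to 1.97-fold downward. Of these, 2 of the 10 higher and 6 of the 10 lower probes exceeded the 95th percentile of the negatives on all 6 arrays, against 2313 of all 14062.

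**Figure D2:**
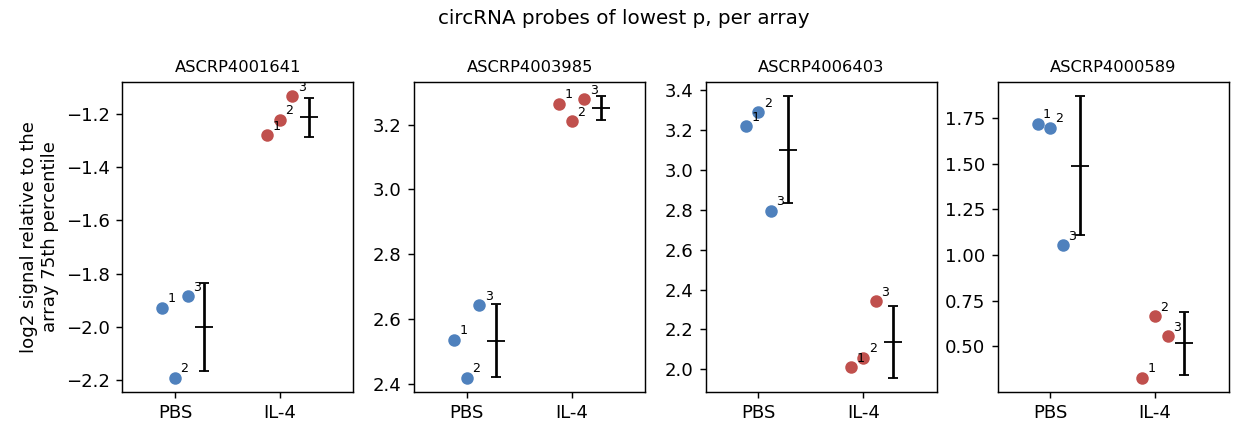
Log2 signal relative to the array's 75th percentile (y axis) in the PBS and IL-4 groups (x axis) for the 2 circRNA probes of lowest p in each direction, one panel per probe with its own y range. Points are arrays, numbered by replicate, and the black bar is the mean ± SD (n = 3). The probes were chosen among those whose groups do not overlap, and none passes the adjustment (limma adjusted p = 0.247).

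The number of circRNAs called depended on one array. Without PBS replicate 3, limma called 412 probes at an adjusted p under 0.05, 244 higher and 168 lower in IL-4, with a median difference of 1.61-fold. Without any one of the other 5 arrays, 0 probes were called. With array weights, which gave PBS replicates 2 and 3 the lowest weights (0.45 and 0.43), 180 probes were called. The 4 arrays of the first position row (3 IL-4 and PBS replicate 1) gave 85 calls, in a fit where the lone PBS array is assumed to vary like the IL-4 arrays. With the position row as a block, 0 were called, and the second row held PBS arrays only.

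**Figure D3:**
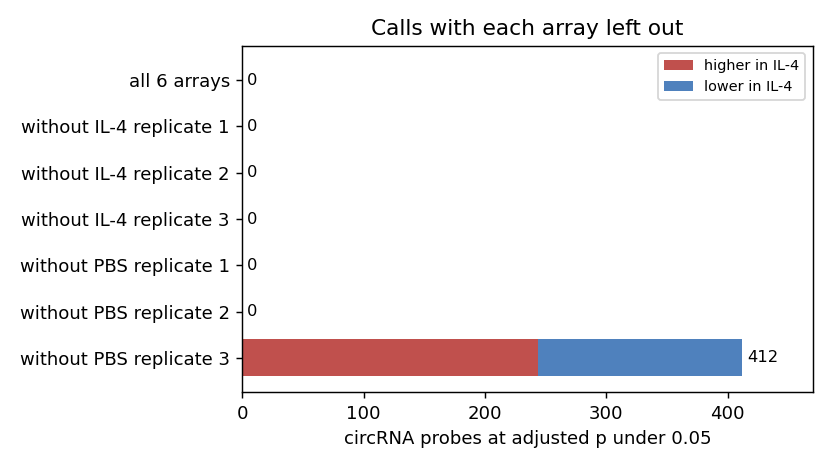
Number of circRNA probes at an adjusted p under 0.05 (x axis) with all 6 arrays and with each array left out (y axis), split into higher (red) and lower (blue) in IL-4. Only leaving out PBS replicate 3 gives calls, 244 higher and 168 lower.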

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

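The array position test, the counts of splits for circRNA probes and the tests on probes chosen without an IL-4 replicate were chosen after the results were seen; the other tests below were set out before theirs.

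Of the 94 design probes outside the circRNA comparison, 3 differed between IL-4 and PBS past the adjustment over those 94 (limma, adjusted p under 0.05). One of the 14 circRNA controls was higher in IL-4 by 0.73 on the log2 scale (1.66-fold, limma adjusted p = 0.0135). One catalogue-style probe was higher by 0.84 (limma adjusted p = 0.0298), and another had a log2 difference of -0.69 (limma adjusted p = 0.0298). In all 3 the IL-4 and PBS arrays did not overlap, with PBS replicate 3 on the side of the PBS arrays. The 3 passed under each of the 3 scalings tried (75th percentile, circRNA median, none). With one array left out at a time, the 3 no longer passed without IL-4 replicate 1, 2 or 3 or PBS replicate 1, and the lower catalogue-style probe also not without PBS replicate 2. The circRNA control and the higher probe thus missed the threshold in 4 of 6 cases and the lower probe in 5 of 6, with adjusted p of up to 0.117, 0.151 and 0.169. Their log2 differences stayed between 0.67 and 0.77, between 0.69 and 0.95, and between -0.78 and -0.56.

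The absence of calls with all 6 arrays against 412 without PBS replicate 3 is the pattern that most affects the comparison. A position row effect that makes arrays of one row alike is argued against as the main cause. PBS replicate 3 correlated with PBS replicate 2 of its own row at 0.962, below its lowest correlation with the other row (0.979). PBS replicate 2 was itself far from the IL-4 arrays (0.967 to 0.978), so a lesser row effect stays open. A wrong label on PBS replicate 3 stays open. Over the 412 probes its median position was 0.97 on a scale from 0 (mean of PBS replicates 1 and 2) to 1 (IL-4 mean), but probes called only without that array mostly have it away from the other PBS arrays, so this value largely restates the pattern. At the PBS level (below 0.2) it lay in 23 of the 412, where 1000 draws of it as an IL-4 array gave at most 3 at their 95th percentile. The draws do not exclude a wrong label either, because an array labelled IL-4 can lie there more often than they allow. Over 826 probes that differed between IL-4 replicates 1 and 2 and PBS replicates 1 and 2 (unadjusted p under 0.05, at least 1.5-fold), chosen without the other 2 arrays, 11.1% had IL-4 replicate 3 below 0.2 and 5.45% had PBS replicate 3 there. With IL-4 replicates 1 and 2 left out of the choice in turn, 2.37% and 0.44% had that array below 0.2, against 7.37% and 6.59% for PBS replicate 3. By the bounds set beforehand scaling is undecided: quantile normalization left 0.35 times as many calls, 144, of which 138 were among the 412. The pattern itself held under quantile normalization and in the deposited value table. Each gave 0 calls with all 6 arrays, against 144 and 527 without PBS replicate 3. These counts argue against the percentile scaling as the only cause of the pattern. Each comes from quantile-normalized values, so a part played by scaling in general stays open. Differences between the cultures other than IL-4, and between the arrays, stay open as untested.

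With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Any split reaches the real 0 calls, so that all 10 did decides nothing, and the highest other split gave 185. For probes at an unadjusted p under 0.05 and at least 1.5-fold, 2 of the 10 splits reached the real 112, and the highest other gave 346. For the design probes, 2 of the 10 reached the real 3, and the highest other gave 9. Each of these highest counts came from the split that exchanges IL-4 replicate 3 with PBS replicate 3. This points to a structure of the samples or of the arrays along that split, and the 2 were not told apart. If the labels of IL-4 replicate 3 and PBS replicate 3 had been exchanged, that split would be the treatment. Over the 826 probes chosen without both, IL-4 replicate 3 had a median position of 0.52 and PBS replicate 3 of 0.86. An exchange would move IL-4 replicate 3 toward 0 and PBS replicate 3 toward 1, and correct labels the reverse. Choosing probes by unadjusted p from the remaining arrays can also draw both held-out arrays toward the middle, so neither position has a fixed reference. Exchanged labels and another difference between the samples or arrays cannot be told apart by these values.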

How the results depend on the processing

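The count of 0 circRNA probes at an adjusted p under 0.05 held under the other scalings, the background corrections, the deposited value table, the dim-probe filters, the trended and robust fit and an adjusted p under 0.1, with limma throughout. It became 180 with array weights and 85 with the first position row alone, and it ranged from 0 to 412 with one array left out. Without PBS replicate 3 it was 144 with quantile normalization and 527 in the deposited value table. The 112 probes at an unadjusted p under 0.05 and at least 1.5-fold became 23 with normexp and percentile scaling, 24 with normexp and quantile normalization, 51 in the deposited value table, 288 with array weights, 35 above the negatives (where 2734 probes were tested), 353 with the position row as a block, 448 with the first row alone and 2 at 2-fold. They ranged from 81 to 495 with one array left out, with 235 without IL-4 replicate 3. Without PBS replicate 3 they were 445 with quantile normalization and 272 in the deposited value table. The causes of these changes were not tested. Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at -0.20, -0.28 and -0.36, and the replicate block gave 0 calls and 132 probes at the unadjusted threshold. The mean correlation across groups moved by less than its SD. The 4 named probes kept their direction under every alternative run, but the log2 difference of ASCRP4001641 (0.79) fell to 0.40 with normexp and percentile scaling, 0.36 with normexp and quantile normalization and 0.55 in the deposited value table. Each of the 4 had an adjusted p under 0.05 in 4 or 5 of its 23 or 24 alternatives. All of these left out PBS replicate 3 or, with array weights, gave it the lowest weight (0.43), so they are not separate support. A slide block was not run, since the arrays share 1 scan time. Host gene, gene list and circRNA class results were not run, for want of probe annotation. Signal over background limits the rest: most circRNA probes lie below the brightest negative. Only 9.12% to 16.8% per array lie below the negatives' median.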

Other observations

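The ranking of probes against a circRNA control was chosen after their similarity was seen. A pair of circRNA probes and a circRNA control, all with higher values in IL-4, had closely similar profiles over the arrays. The circRNA probes were those ranked 2 and 3 by p among probes higher in IL-4 without overlap between the groups. These, ASCRP4003985 and the one after it, differed by 0.72 each on the log2 scale. The circRNA control past the adjustment over the design probes differed by 0.73. When 14057 circRNA probes were ranked by how little their difference to the control varied over the 6 arrays, these 2 probes ranked 1 and 2, with SDs of 0.04 and 0.05 against a median of 0.42 over all probes. Because they had been picked for their similar array values, the ranking restates that similarity and could only have argued against the hypothesis of one shared RNA. A shared RNA and separate RNAs that vary together cannot be told apart without the probes' target sequences, which were not used here.

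In the 50 catalogue-style probes, which are not among the circRNA probes, PBS replicate 3 also lay beside IL-4 replicates 1 and 2. On the first component of these probes alone, IL-4 replicates 1, 2 and 3 scored -1.26, -1.40 and 0.24, and PBS replicates 1, 2 and 3 scored 0.67, 2.95 and -1.20. The probes were not scaled to equal variance, and A_51_P348334 and A_51_P362554 varied most (SD among PBS arrays 1.29 and 0.97). In the 15 negatives, IL-4 replicates 1, 2 and 3 scored -0.19, -0.31 and -0.03, and PBS replicates -0.08, 1.20 and -0.58. PBS replicate 3 also had a negative score in the custom probes (-0.62) and the circRNA controls (-0.45), as did IL-4 replicates 1 and 2. The 15 negatives deviated from their mean by a median of -0.30 on PBS replicate 2 and 0.14 on PBS replicate 3 on the log2 scale, and by 0.00 to 0.08 on the other 4 arrays. The brightest 10% of circRNA probes deviated by a median of 0.17, 0.05 and -0.07 on IL-4 replicates 1, 2 and 3, and by -0.13, -0.12 and 0.07 on PBS replicates 1, 2 and 3.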
